A study of Mus musculus with 3 samples.

How the data were processed

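H3K4me3, a histone mark of active and poised promoters, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in hippocampus from adult male mice. One library came from N171-82Q transgenic mice, a Huntington's disease model that expresses an N-terminal fragment of mutant huntingtin (HD library), and 1 from wild-type littermates (WT library). Per the labels' protocols, the tissue was crosslinked with formaldehyde and the sonicated chromatin was precipitated with an antibody against H3K4me3. Per the series' design text, each immunoprecipitation used hippocampi pooled from 3 mice and libraries were read as single ends of 50 bp. An input DNA library belongs to the series, and its data were not used here. The labels state that the raw reads of the WT and input libraries also belong to an earlier deposit; they make no such statement for the HD library, and they give no sequencing date or batch.

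The authors deposited 1 list of peaks per library, with the position of each peak and a score. The peak names in the files carry the name of the peak caller MACS. The version of MACS, its settings and whether the input served as its control are not given in the sources used here. The submitters' processing notes name CASAVA 1.8.2, BWA 0.5.9 and SAMtools, and the mouse genome builds NCBIM37 and mm9, which are 2 names of the same assembly. The deposited score runs from 50.01 to 3233.06 in both lists, and 448 WT peaks and 2184 HD peaks share the value 3100. This pattern is that of the minus 10 times log10 p-value that MACS writes, although the files do not name the unit. Such a score depends on the depth of its own library, so scores were used only to rank, describe and filter peaks within a list. The files give no read counts, so the depth of the libraries is unknown. Peaks were called per library, each from 1 pool of animals.

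Peak positions were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. A peak had a counterpart when it overlapped a peak of the other list by at least 1 bp. Overlapping peaks of the lists were joined into regions, and the length that each library's peaks covered in a region was compared as the log2 of HD over WT. Chance overlap was estimated from 100 random circular shifts of a list within each chromosome. Intervals for shares are exact (Clopper-Pearson) 95% binomial intervals, and those for medians are 95% order-statistic intervals. They cover counting error over peaks only and say nothing about variation between mice. With 1 library per genotype there was no replicate check, and no p-value was computed. On simulated lists made from the WT list, the procedure recovered 1000 of 1000 removed peaks, 1500 of 1500 added peaks, and a median log2 length ratio of -0.15 against the -0.15 simulated. Kept peaks always overlapped there and added peaks never did. The simulation thus checks the code only, not the handling of divided peaks or of libraries that differ in depth.

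Before the data were examined, the designs, the alternatives and the rule for named regions were fixed. The rule names the 4 highest scoring peaks of each list, the 10 highest scoring peaks of each list that lie over 1 kb from any peak of the other list, and the 8 shared regions with the largest gain and the 8 with the largest loss of covered length, among those with a mean length of at least 1 kb. Ties in score were broken by width. Any region named outside this rule is marked as chosen after its values were seen. The alternatives were other overlap rules, a minimum score of 100, equal numbers of top scoring peaks, autosomes only, and joining peaks within 1 kb.

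Genes were not assigned to peaks. The only gene table used covers assembly GRCm38.p6, another build than that of the peaks. Of 21887 protein-coding genes in that table, 8.79% had an end inside a WT peak, against a median of 3.21% when all genes were moved by 5 to 20 Mb. The planned counts of promoters with a peak and the comparison of 17 gene lists, including Htt and Prnp, were therefore not analysed here. Regions are given by their mm9 coordinates, counted from 1. Whether a region lies in a promoter, exon or intron was not analysed here.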

Results

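The data set held 2 H3K4me3 peak lists from adult mouse hippocampus, 1 from N171-82Q transgenic mice and 1 from their wild-type littermates, each made from a pool of 3 animals. The comparison asked where H3K4me3 differed between the hippocampus of a Huntington's disease model and that of healthy littermates. No genotype had a second library, so every difference below describes this pair of libraries, and none could be set against a spread between replicates.

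H3K4me3 formed peaks of a few kilobases on every chromosome in both libraries. The WT library had 18515 peaks covering 45.8 Mb, and the HD library had 19631 peaks covering 43.8 Mb. The HD library thus had more peaks over a shorter total length. The median peak width was 2268 bp in the WT library (quartiles 1587 and 3014 bp) and 2054 bp in the HD library (quartiles 1395 and 2761 bp). Peaks of 4 kb or wider made up 9.55% of the WT list, 1768 peaks, and 6.63% of the HD list, 1301 peaks. The widest peak spanned 23847 bp in WT and 14067 bp in HD. In the region of that WT peak the HD library had 4 peaks covering 21899 bp. Such widths thus also depend on how a region was divided into peaks. Chromosome 2 carried the most peaks in each list, 1443 in WT and 1555 in HD, followed by chromosome 11 with 1403 and 1505. The X chromosome carried 576 and 603 peaks. On the Y chromosome the WT list had 4 peaks, all with an HD counterpart, and the HD list had 1 more, at position 145389 to 146132 with a score of 64.65, named after its values were seen.

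The authors' score had a median of 843 in the WT list and 1144 in the HD list, each on the scale of its own list. Many peaks shared the value 3100, 11.1% of the HD list and 2.42% of the WT list, and 277 HD peaks and 104 WT peaks scored above it. Ranks at the top of the lists therefore carry little information. At the maximum of 3233.06 were 6 WT peaks and 5 HD peaks. The 4 widest of these in the WT list lay on chromosome 4 at 82142377 to 82155417 and at 106849767 to 106853150, on chromosome 2 at 116944948 to 116950365, and on chromosome 9 at 90006907 to 90010633. In the HD list they lay on chromosome 6 at 125094720 to 125100083, on chromosome 10 at 74522177 to 74527205 and at 77812599 to 77816138, and on chromosome 7 at 139506585 to 139509877. All 8 overlapped a peak of the other library. The first WT peak was 13041 bp wide, and the HD peak over it covered 12246 bp.

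The sets of marked regions were largely the same in the mutant and wild-type hippocampus. Of the WT peaks, 17496 overlapped an HD peak, 94.5% (95% interval 94.2 to 94.8%). Of the HD peaks, 17806 overlapped a WT peak, 90.7% (90.3 to 91.1%). When a list was shifted at random along the chromosomes, the median overlap was 3.60% for WT peaks and 3.43% for HD peaks. Without a counterpart were 1019 WT peaks and 1825 HD peaks. With a minimum score of 100 in both lists these counts were 399 and 1281. They then include peaks whose only counterpart scored below 100. This cutoff falls unevenly on the lists: among peaks with a counterpart, 1872 WT peaks and 1420 HD peaks scored below it. With counterparts of any score the counts were 107 and 375. With equal numbers of top scoring peaks they were 1360 and 1146; at equal list lengths their order is set by how many peaks each library has in the shared regions.

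Peaks found in 1 library were weak. Their median score was 64.9 in WT and 69.4 in HD, close to the lowest score of 50.01 in each list, and their median widths were 1130 and 1035 bp. Peaks with a counterpart had median widths of 2335 and 2163 bp. Most of this gap in width went with the score: among peaks with a score below 100, those without a counterpart had median widths of 1105 bp in WT and 998 bp in HD, and those with one 1213 and 1042 bp. In the lowest decile of scores, 60.0% of WT peaks (57.8 to 62.3%) and 43.4% of HD peaks (41.2 to 45.6%) had a counterpart. In the third decile these shares were 98.5% and 94.2%. Among peaks with a score of at least 200, 3 of 13753 WT peaks and 23 of 14705 HD peaks had none. Above a score of 1000, none of 8228 WT peaks and none of 10418 HD peaks lacked a counterpart. Restricting the lists to scores of at least 100, with counterparts of any score, left 107 WT-only and 375 HD-only peaks.

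**Figure D1:**
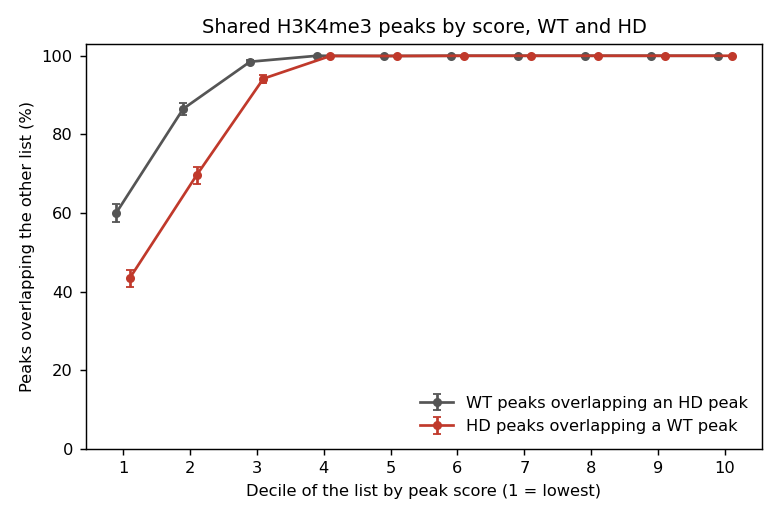
Share of peaks (%) that overlapped a peak of the other library by at least 1 bp, for each decile of the WT list (grey) and the HD list (red) ranked by the authors' score, with exact 95% binomial intervals as bars. The share rises from 60.0% (WT) and 43.4% (HD) in the lowest decile to 98.5% and 94.2% in the third.

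A few regions stood apart from the weak ones. The highest scoring HD-only peak lay on chromosome 2 at 131762440 to 131765960, was 3521 bp wide and had a score of 698.55. The nearest WT peak was 14.6 kb away. Of the 1333 HD peaks with a score within 1.25-fold of it, this was the 1 without a counterpart, and it was wider than 94.8% of them. The next HD-only peak, on chromosome 12 at 34641441 to 34644200, had a score of 346.89 and a width of 2760 bp, with the nearest WT peak 363 kb away. The other 8 named HD-only peaks had scores from 230 to 280 and lay 1.91 to 1545 kb from the nearest WT peak. Among them, that on chromosome 7 at 31697282 to 31699891 was 2610 bp wide, that on chromosome 17 at 93601196 to 93603652 was 2457 bp wide, and that on chromosome 9 at 87623974 to 87626429 was 2456 bp wide. Chromosome 17 held 2 more, at 56256401 to 56257361 and at 35575455 to 35576720. The remaining 3 were on chromosome 3 at 107385259 to 107386632, on chromosome 11 at 101309457 to 101310743 and on chromosome 1 at 182723584 to 182724851. The peak on chromosome 9 had the lowest score of those named, and 38 of 1115 HD peaks within 1.25-fold of that score lacked a counterpart.

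The highest scoring WT-only peak lay on chromosome 9 at 24345993 to 24346820, with a score of 622.14 and a width of 828 bp. WT peaks with a score within 1.25-fold had a median width of 2193 bp, and 0.059% of those 1691 peaks were narrower. The nearest HD peak was 37.4 kb away. The next WT-only peak, on chromosome 10 at 5056483 to 5058886, had a score of 225.93 and a width of 2404 bp. The other 8 named WT-only peaks had scores from 173 to 194 and widths of 1120 to 2563 bp. They lay on chromosome 14 at 21435783 to 21438345, on chromosome 17 at 51899525 to 51901125 and 83944698 to 83946295, on chromosome 6 at 93015537 to 93017083 and 65768074 to 65770029, on chromosome 18 at 64625585 to 64626704, on chromosome 9 at 105422760 to 105424091 and on chromosome 11 at 111384057 to 111385318.

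**Figure D2:**
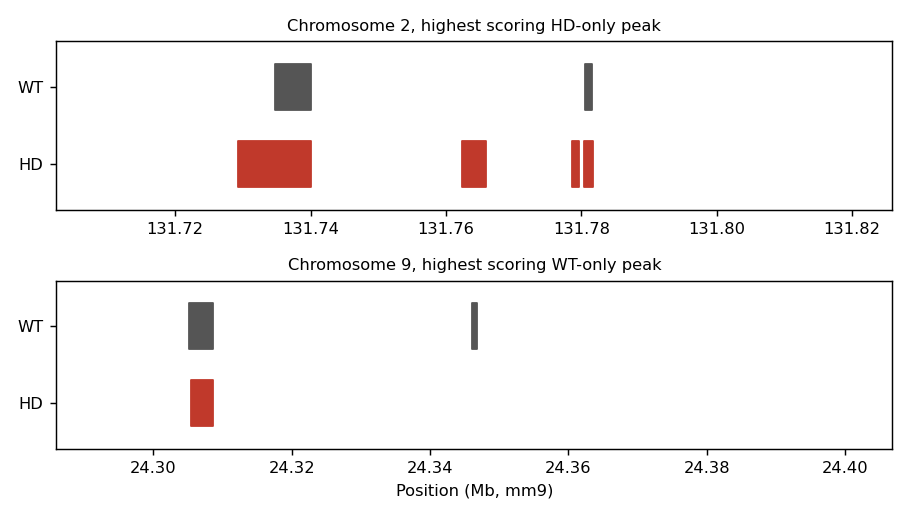
Peaks of the WT (grey) and HD (red) libraries over mm9 positions (Mb) within 60 kb of the highest scoring HD-only peak on chromosome 2 and of the highest scoring WT-only peak on chromosome 9; each bar spans 1 peak. On chromosome 2 the HD library has a peak at 131762440 to 131765960 that the WT library lacks. A weaker HD peak at 131778572 to 131779699 overlaps no WT peak but has 1 within 1 kb. The peak to the left of both covers 10739 bp in HD and 5312 bp in WT. Whether sequence of the transgene construct adds to these HD peaks was not checked here.

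Library-specific peaks were spread over all autosomes. By chromosome, 3.87 to 7.87% of WT peaks and 6.94 to 11.6% of HD peaks on autosomes had no counterpart. On the X chromosome, 13 of 576 WT peaks were specific, 2.26% (1.21 to 3.83%), against 5.61% (5.28 to 5.96%) on the autosomes together. For HD peaks the X chromosome share was 6.97% (5.07 to 9.30%), against 9.37% (8.96 to 9.79%). Within the lowest 3 deciles of scores, 7.56% of WT peaks on X (4.09 to 12.6%) and 18.7% of those on autosomes (17.6 to 19.7%) were specific. For HD peaks these shares were 25.0% (18.7 to 32.3%) and 31.1% (29.9 to 32.3%), and the interval for X held the autosomal value.

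**Figure D3:**
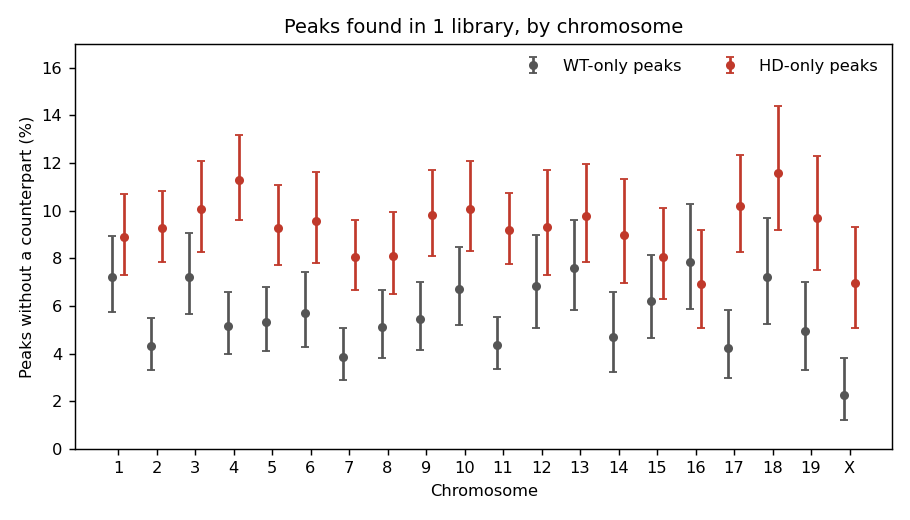
Share of each chromosome's peaks (%) without a counterpart in the other library, for WT peaks (grey) and HD peaks (red), with exact 95% binomial intervals as bars. The X chromosome has 2.26% for WT peaks, below the 3.87 to 7.87% of the autosomes.

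Where both libraries had H3K4me3, the HD peaks were slightly shorter. The lists formed 20211 regions, of which 17367 were shared, and 97.2% of these held exactly 1 peak of each library. The median log2 ratio of HD over WT covered length was -0.090 (95% interval -0.093 to -0.087; quartiles -0.22 and 0.03), that is 6.04% less in HD. The HD library covered less in 11991 shared regions, 69.0%, and more in 5351, 30.8%. In regions with 1 peak of each library, the HD edge lay inward by a median of 62 bp on the left and 64 bp on the right. These medians do not mean that single peaks shrank at both ends. Both HD edges lay at or inside the WT edges in 42.7% of these regions and at or outside them in 13.1%. Medians ranged from -0.12 to -0.07 over the 19 autosomes and X, and every interval lay below 0. Over deciles of region length the median was -0.13 in the shortest decile and between -0.10 and -0.07 in the others.

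**Figure D4:**
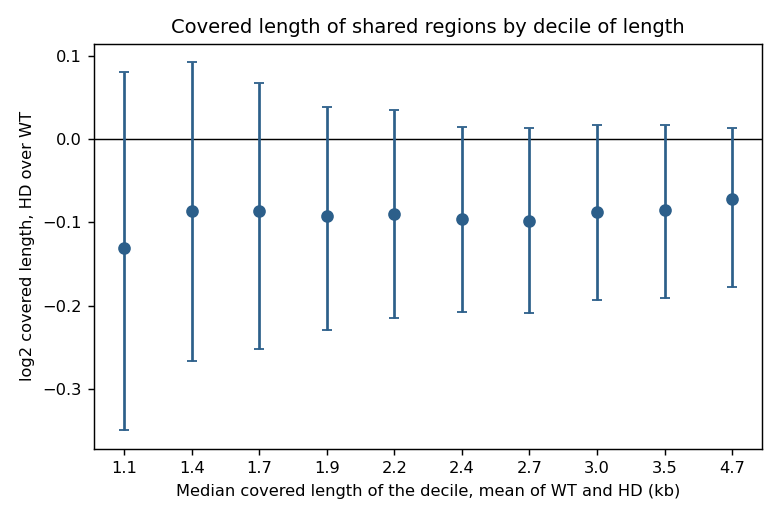
Median log2 ratio of covered length, HD over WT, in shared regions grouped in deciles by their mean length (x axis: median length of the decile in kb); bars are the quartiles over regions. All medians lie below 0, from -0.13 in the shortest decile to -0.07 in the longest.

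Large differences in covered length were few. More than 1.5-fold shorter in HD were 485 regions, and more than 1.5-fold longer were 130. With a minimum score of 100 in both lists these counts were 379 and 80, and with peaks within 1 kb merged they were 511 and 185. Beyond 2-fold, 51 were shorter and 18 longer. These cutoffs lie evenly about 0 while the median log2 ratio was -0.090, so some excess of shorter regions follows from the general shift. The largest gains lay on chromosome 14 at 52946381 to 52948426, with 652 bp in WT and 2046 bp in HD (log2 ratio 1.65), and on chromosome 5 at 102091870 to 102094980, with 1053 and 3042 bp (1.53). Gains with log2 ratios of 1.23 to 1.43 lay on chromosome 11 at 11936218 to 11938168, chromosome 1 at 157588332 to 157590610 and 155512187 to 155515149, chromosome 14 at 52627812 to 52630625, chromosome 4 at 40419134 to 40422229 and chromosome 2 at 20467965 to 20470042. In 7 of these 8 regions the WT peak had a score below 100.

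The largest losses lay on chromosome 4 at 97448685 to 97452950, with 4266 bp in WT and 889 bp in HD (log2 ratio -2.26), and on chromosome 2 at 20881881 to 20885732, with 3795 and 836 bp (-2.18). Losses on chromosome 12 at 88234264 to 88237013 and on chromosome 3 at 60333534 to 60335973 had log2 ratios of -1.52 and -1.26. These 4 depended on how peaks were joined: with peaks within 1 kb merged they became -0.49, -0.84, -0.53 and -0.53. The other losses had ratios of -1.42 to -1.25, on chromosome 9 at 32031172 to 32033951, chromosome 2 at 90804697 to 90807075, chromosome 10 at 79376915 to 79382259 and chromosome 6 at 30623707 to 30626139. The chromosome 10 region had 5345 bp and a score of 730.87 in WT and 2120 bp and a score of 1923.51 in HD. In 5 of the 8 regions the HD peak had a score below 100.

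Wide H3K4me3 regions, which in many tissues lie over cell identity genes, were also shorter in HD, by a slightly smaller proportion than the others. The widest 5% of shared regions, 869 regions with a mean length of at least 4.71 kb, had a median log2 ratio of -0.07 (-0.07 to -0.06), against -0.09 (-0.10 to -0.09) in the other 16498. Of the wide regions, 28.0% (25.0 to 31.1%) were longer in HD, against 31.0% (30.3 to 31.7%) of the others. The widest region, on chromosome 13 at 83852345 to 83876218, was 1 WT peak of 23847 bp and 4 HD peaks covering 21899 bp. On chromosome 12 at 50474576 to 50489818, 1 WT peak of 15243 bp faced 4 HD peaks covering 14143 bp. On chromosome 15 at 85499110 to 85516810 both libraries had 2 peaks, covering 17072 bp in WT and 17626 bp in HD. Chosen after their values were seen, these 3 are the widest shared regions. HD had more peaks than WT in 19.2% of the wide regions and fewer in 2.99%. With peaks within 1 kb merged the first share was 5.28%, and with a minimum score of 100 in both lists it was 12.4%. In the other regions as deposited, HD had more peaks in 1.23% and fewer in 0.333%.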

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

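All alternatives here were planned before the data were examined. The share of WT peaks with a counterpart, 94.5% as deposited, was 94.0% when 50% of the peak had to be covered, 93.1% with a reciprocal overlap of 50%, 95.05% with any peak within 1 kb, 94.9% after merging peaks within 1 kb and 92.7% with equal numbers of top scoring peaks. It was 99.3% for WT peaks with a score of at least 100 and 97.5% with that minimum in both lists. The share of HD peaks, 90.7% as deposited, was 87.8% with reciprocal overlap, 91.4% with any peak within 1 kb, 93.8% with equal numbers, 97.8% with a minimum score of 100 in the HD list and 92.4% with the minimum in both. With equal numbers the order of the shares turned, which says nothing about list length: the lists are then equal, and the order is set by how many peaks each has in shared regions. Counts of peaks without a counterpart, 1019 WT and 1825 HD as deposited, were 1275 WT and 2391 HD peaks with reciprocal overlap, 107 WT and 375 HD peaks with the minimum in the list counted, 399 WT and 1281 HD peaks with it in both lists, and 1360 WT and 1146 HD peaks with equal numbers. The median log2 length ratio stayed between -0.091 and -0.088 and the share of wide regions longer in HD between 26.1 and 30.5% under every alternative run. The count of regions over 1.5-fold longer in HD fell from 130 to 80 with a minimum score of 100 in both lists and rose to 185 with peaks within 1 kb merged. That minimum left 12 of the 17 regions named for a length change, the chromosome 2 region outside the rule included, without a peak in both lists, and equal numbers left 4, among them both largest losses. The analyses of promoters and gene lists were not run, because no annotation of the peaks' genome build was used here. No paired analysis was possible because each genotype has 1 library. The unknown depth of the libraries limits what an absent weak peak can show.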

Other observations

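The tests below were chosen after the results had been seen, except those of neighbouring peaks and of the gaps in divided peaks. The locus on chromosome 2 that held the strongest HD-only peak carried a second difference, outside the rule for named regions. At 131729324 to 131740062 the HD peak covered 10739 bp and the WT peak 5312 bp. The extra length lay almost wholly on the left, where the HD peak began 5.36 kb before the WT peak, while the right edges differed by 70 bp. Among the 8223 shared regions with a WT score of at least 1000, this gain ranked first, at a log2 ratio of 1.02; among all 17367 shared regions it ranked 18. The score class was chosen after the values were seen, as were the regions named in this paragraph. The next gain was 0.81, on chromosome 11 at 102290550 to 102294846, and the SD over the regions of this class was 0.18. Some losses in the class were larger in size, with log2 ratios of -1.18 on chromosome 18, -1.15 on chromosome 5 and -1.04 on chromosome 3. The locus on chromosome 2 spans 36.6 kb from the start of the longer HD peak to the end of the HD-only peak. Between these peaks lie 22.4 kb. The same window held a weak HD peak that no WT peak overlapped, at 131778572 to 131779699 with a score of 71.43. A WT peak began within 1 kb of it, at 131780583, so under the rule of any peak within 1 kb it had a counterpart.

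Calls that differ by sampling stay open for the HD-only peak on chromosome 2. Of the 1332 other HD peaks of like score, 0 lacked a counterpart, which allows a share of up to 0.225%, but the peak was picked as the highest scoring of its kind, so this decides nothing. Among peaks with a score of at least 500, 1 of 12514 HD peaks and 1 of 11321 WT peaks had no counterpart. These 2 peaks differ in width, 3521 bp in HD and 828 bp in WT. The N171-82Q transgene is driven by sequence of the mouse prion protein gene, Prnp, which lies on chromosome 2. Reads from the construct would align to the native gene and add signal there in HD only. The hypothesis that construct sequence may explain both the peak and the gain with the log2 ratio of 1.02 was formed from these values, which therefore do not test it. It stays open: the position of Prnp in mm9 was not checked here, and a local duplication or a true change of the mark could give such values too.

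Most library-specific peaks were weak: 99.9% of the 1019 WT-only and 1825 HD-only peaks lay in the lowest 3 deciles of their own list's scores (interval 99.69 to 99.98%). This share restates the pattern, so it does not separate calls that differ by sampling near the threshold from real differences at weak peaks, and both stay open. The ratio of HD-only to WT-only peaks was 1.79, from 1825 and 1019 peaks. With a minimum score of 100 in both lists the counts were 1281 and 399, which include peaks whose only counterpart scored below 100. Among peaks with a counterpart, that cutoff removed 1420 HD peaks and 1872 WT peaks. With counterparts of any score the counts were 375 and 107. With equal numbers of top scoring peaks their order turned, to 1146 and 1360. With 1 library per genotype an effect of genotype on these weak peaks cannot be told apart from that of the library.

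The shorter HD regions were weighed against 2 technical explanations. A fixed length trimmed from every peak, as a fragment length setting could give, would take about the same length at every width. In regions with 1 peak of each library, the median loss in the widest decile, 228 bp, was 2.42 times that in the narrowest, 94 bp (bootstrap interval 1.96 to 2.96). This argues against an even trim of these regions as the whole cause. Regions lost from a list do not enter, and a setting that acts unevenly stays open. The narrowest peak was 497 bp in WT and 290 bp in HD. Fewer reads or weaker enrichment in HD stays open. The HD list held 1.06 times as many peaks (1.04 to 1.08, counting only). Peaks with a counterpart had median scores of 1367 in HD and 919 in WT, but each value is on the scale of its own list. These values do not decide it, because the depth, the settings and the control are unknown. A deeper library with weaker enrichment could also give more peaks. Differences of fragmentation or background stay open too. With a median log2 ratio of -0.09 from 1 library per genotype, genotype and library cannot be told apart.

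Single WT peaks were divided into several HD peaks in 367 regions, and single HD peaks into several WT peaks in 80. The median gap between the HD pieces was 132 bp (114 to 148 bp), against a general median shortening of 143 bp. The gap between the WT pieces was 77.5 bp (45 to 94 bp), also short although WT peaks were the longer ones, so the gaps do not show whether shortening alone divided the peaks. HD-only peaks had 308 neighbouring pairs within 100 kb, against a median of 278 in 1000 draws of HD peaks of like score, of which 14 had as many. WT-only peaks had 91 pairs, against a median of 84, and 205 draws had as many. Such a count over the whole genome would hardly move for 1 segment with a few peaks. A linked segment that differs between the mice thus stays open for both lists. Some windows of 1 Mb, chosen after their values were seen, held many such peaks. On chromosome 18 at 69000001 to 70000000, 6 of 22 WT peaks were WT-only, and on chromosome 13 at 84000001 to 85000000, 5 of 9. On chromosome 18 at 37000001 to 38000000, 8 of 26 HD peaks were HD-only and 4 of 21 WT peaks were WT-only. Picked for their counts, these windows test nothing.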
